A study of Mus musculus with 12 samples.

How the data were processed

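Venous RNA of 12 mouse samples, 6 sham and 6 AVF-CKD, was sequenced on an Illumina HiSeq instrument after library preparation with the TruSeq RNA kit, per the labels' protocols. The groups and numbers were taken from the sample titles. The deposited table gave, per gene, a read count and an RPKM value for each library. The submitters' processing notes name the genome build GRCm38 and the tools TopHat2 2.1.0, featureCounts and edgeR, without saying which step each performed. The annotation release, the strand setting and read filters are not given in the sources used here. The deposited counts were whole numbers per gene and were analysed as deposited. The deposited RPKM values divide the counts by the length given in the table and by a library total that was 1.15 to 1.19 times the sum of counts, as worked out from the file, and they were not used for tests. Because TruSeq libraries of this kit do not mark strand, reads of overlapping genes on opposite strands cannot be told apart.

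Of the 43346 genes, 42462 identifiers were found in the GENCODE M21 annotation of GRCm38. The 37 mitochondrial genes had 0 counts in all libraries, which for this table means that their reads were not counted there. The 10 nuclear models that copy mitochondrial sequence held 2.08% to 3.84% of the counts, and the 2 models at a ribosomal DNA copy on chromosome 17 (Yam1, 39846958 to 39848788, and AY036118, 39847526 to 39848829) held 3.89% to 7.46%. There were 12 models with 1000 or more counts whose counts equalled those of another model in all 12 libraries. Gene length was that given in the deposited table, and GC content that of the longest GENCODE transcript. For each named gene the share of exonic bases overlapped by other GENCODE models was computed. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 48.3 to 215 over 66 pairs). The number of per-sample columns of other series was 0.

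Counts were filtered with filterByExpr by group, scaled with TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with the group as the single term. P-values were adjusted by Benjamini-Hochberg and called below 0.05. Standard errors came from the fold change and its F statistic, and 95% intervals from the same fit. The common dispersion was 0.0588, a biological coefficient of variation of 24.2%. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Gene lists (38, of which 37 had 5 or more tested members) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. They covered the vessel wall and endothelium, matrix, leukocytes and inflammation, interferon, proliferation, metabolism and stress, calcification, genes often followed in fistula stenosis, the clock, and tissues that could be carried along: fat, skeletal and cardiac muscle, blood, lymphatics, nerve and neck glands. Members can stand in more than a single list.

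Genes were named by a rule fixed before the data were examined. Parts for called genes named none, since 0 were called. The rule then took the most abundant member of each list and the 3 genes with the smallest p in each direction, leaving out immunoglobulin and T-cell receptor segments and models without a proper name. Some genes that the rule names are not reported here. Arg1, Mmp9, Mertk, Itgam, Ccl12, Cxcl12, Retn, Adipoq, Ifit3, Isg15, Ptger3, Postn, Mki67, Tnc, Myh11, Tagln, Cd68, Ckm, Dbp, Arntl, Npas2, Ucp1, Polr2a and Xist, and Rps20, were named after their values were seen.

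Principal components used the 500 most variable genes, and single values were compared by two-sided exact permutation tests over 924 assignments, whose smallest p is 0.00216. Alternatives fixed in advance were other scaling factors, 2 other filters, the title number as a block, 1 surrogate variable (sva 3.50.0), removal of genes of other tissues, DESeq2 1.42.0, limma 3.58.1 voom with sample weights, fold thresholds, other set tests and leaving out each library. Chosen after seeing the data were a clock score, muscle and fat scores, title numbers 1 to 3 against 4 to 6 as a term, and removal of ribosomal and mitochondrial copies. The fit was repeated on 100 of the 462 splits of the libraries into groups of 6, with edgeR and DESeq2, on 100 of the 200 that put 3 libraries of title numbers 1 to 3 and 3 of 4 to 6 in each group, and on the 36 exchanges of 1 library of each group. To remove a trend on gene length or GC content, a smooth curve of each library's deviations was entered as an offset.

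The fits were tested on simulated counts with 200 genes changed, each simulation a single draw. The counts were drawn from the means, library sizes and edgeR-estimated dispersions of these libraries. For the comparison of AVF-CKD with sham (18827 genes) edgeR recovered 34.9%, 73.8% and 90.9% of genes changed 1.5-fold, 2-fold and 4-fold with 4.38% false calls, DESeq2 47.0%, 80.0% and 93.9% with 25.6% false calls, and limma voom 31.8%, 75.4% and 89.4% with 3.73% false calls. A simulated list of 20 genes moved by 0.5 on the log2 scale was called by each set test, with 0 unmoved lists called. The simulated genes varied independently of each other, while estimated correlations within the real lists had a median of 0.318. The count of 0 therefore does not test the preset correlation on lists whose genes vary together. For title numbers (18965 genes) with a simulated trend on length, 43 unchanged genes were called without the correction and 4 with it, and 156 and 154 of the 200 changed genes were called. Intervals cover the spread between libraries and counting error together.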

Results

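RNA-seq libraries from the veins of 12 mouse samples were compared 7 days after surgery. In the sham group (n = 6) the tissue was the jugular vein, and in the AVF-CKD group (n = 6) it was the venous limb of the AVF. The labels do not spell out these letters, which are read here as arteriovenous fistula (AVF), a surgical join between an artery and a vein, and chronic kidney disease (CKD). The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these samples. The deposited table held 43346 genes. Total counts per library ranged from 38.65 to 60.14 M (M, 1e6 counts) and averaged 50.88 M ± 6.81 (SD, n = 6) in sham and 46.53 M ± 4.6 (SD, n = 6) in AVF-CKD, a difference within the spread between libraries (two-sided exact permutation test, p = 0.225, adjusted p = 0.544 over 5 library measures). On this reading the groups differed in surgery and may have differed in vessel and disease model as well, and these cannot be told apart here. The single comparison the labels give is that of the fistula vein with the sham vein.

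Libraries of both groups had the profile of matrix-rich tissue with macrophages. Col3a1, which encodes a fibrillar collagen, stood at 23209 CPM ± 4084 (SD, n = 6) in sham and 24576 CPM ± 5700 (SD, n = 6) in AVF-CKD, and Lyz2, the lysozyme gene of macrophages and neutrophils, at 5709 CPM ± 1677 and 6551 CPM ± 1724. Postn, which encodes the matrix protein periostin, averaged 5945 CPM in sham and 4363 CPM in AVF-CKD. Correlations of log2 CPM between libraries of different groups (median 0.9775) were as high as those within sham (median 0.9775) and close to those within AVF-CKD (median 0.9801). The first principal component held 41.4% of the variance of the 500 most variable genes. All 20 members of the skeletal muscle list were among those genes and loaded on its positive side. Group means on this component differed by -0.30 (two-sided exact permutation test, p = 0.978, adjusted p = 0.978 over 3 components). On the second component, with 13.5% of the variance, the difference was -13.5 (exact permutation p = 0.0195, adjusted p = 0.0585). Sham 6 scored 27 on it, against -2.95 to 9.07 in the other sham libraries, and this test was not repeated without sham 6. The third component, with 10.6%, gave an exact permutation p of 0.558. Distances of libraries to the mean of the other libraries of their group averaged 63.2 in sham and 60.9 in AVF-CKD (exact permutation p = 0.58). This difference was not larger than expected from reassigning the distances between the groups, without computing them anew.

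**Figure D1:**
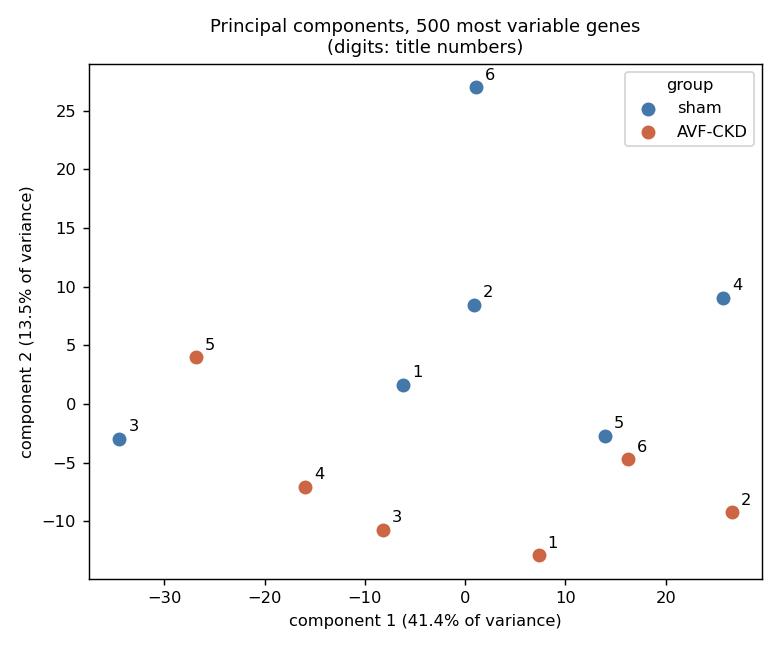
Scores of the 12 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis; points are libraries, colours are groups and digits are title numbers. The groups overlap along the first component (41.4% of the variance).

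No single gene differed between fistula and sham veins at an adjusted p below 0.05 in the edgeR quasi-likelihood test, with 0 of 18965 genes higher and 0 lower in AVF-CKD. At an unadjusted p below 0.05 there were 1772 genes, 998 higher and 774 lower, where 948 would be expected from uniform p-values. The lowest adjusted p was 0.246, for Il6ra, and leaving out AVF-CKD 3 brought this gene to an edgeR adjusted p of 0.0331, the single call made when any of the 12 libraries was left out. limma voom with sample weights also called 0 genes (2124 at an unadjusted p below 0.05), while DESeq2 called 64 higher and 38 lower (2002 at an unadjusted p below 0.05). On simulated counts from these libraries 25.6% of the calls of DESeq2 were false, against 4.38% for edgeR, which recovered 73.8% of the genes changed 2-fold and 34.9% of those changed 1.5-fold among 18827 genes. For 86.7% of the genes tested the 95% interval of the fold change lay within 2-fold in either direction, and for 65.2% within 1.5-fold. The groups did not overlap for 121 genes (0.638%), where chance gives 0.216%.

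The genes with the smallest p-values give the size of the differences that the test left open. Il6ra, which encodes the interleukin 6 receptor (ENSMUSG00000027947, GRCm38 chromosome 3, 89869324 to 89913162), stood at 23.6 CPM ± 2.27 (SD, n = 6) in sham and 34.9 CPM ± 3.17 (SD, n = 6) in AVF-CKD, a log2 fold change of 0.56 ± 0.08 (SE; edgeR adjusted p = 0.246), with every fistula library above every sham library. Pip5k1c, a phosphoinositide kinase gene (chromosome 10, 81292963 to 81319973), had a log2 fold change of 0.31 ± 0.05 and Brinp3 (chromosome 1, 146494760 to 146902472) of 0.99 ± 0.19. Among genes with lower values in AVF-CKD, Gpx8, a peroxidase gene of the endoplasmic reticulum (chromosome 13, 113042763 to 113046388), stood at 142 CPM ± 15.4 in sham and 108 CPM ± 3.93 in AVF-CKD, a log2 fold change of -0.39 ± 0.07 (edgeR adjusted p = 0.349). Mup10 (chromosome 4, 60578260 to 60582199) and Mup14 (chromosome 4, 61300023 to 61304000) had log2 fold changes of -1.39 ± 0.25 and -1.58 ± 0.29, and both are uncertain because they belong to a family of near-identical major urinary protein genes. In each of these 6 genes the groups did not overlap, and DESeq2 gave adjusted p-values from 5.16e-06 for Il6ra to 0.00892 for Mup14. Over all alternatives run, the adjusted p of Il6ra went from that value to 0.638, and that of Mup14 from its DESeq2 value to 0.638.

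**Figure D2:**
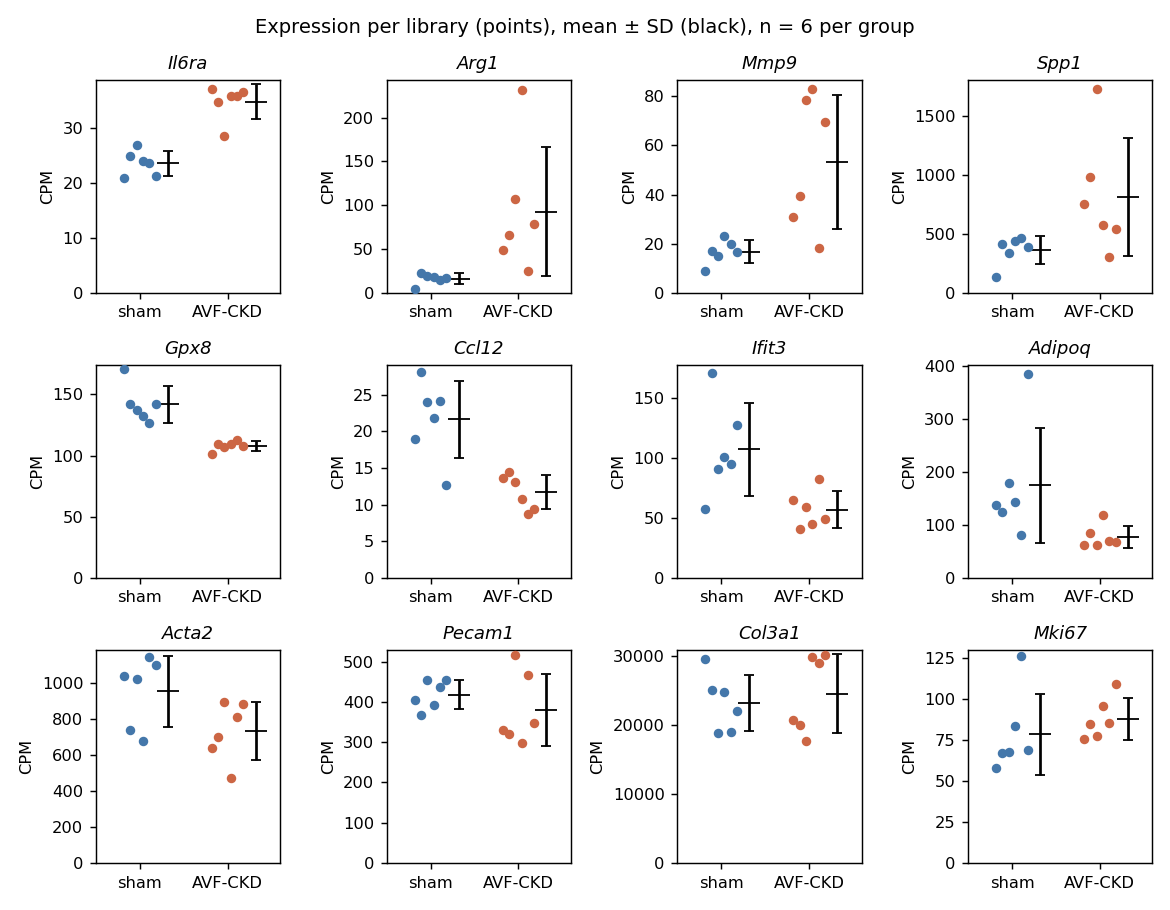
CPM of 12 genes in each library; points are libraries, black bars are the mean ± SD of each group (n = 6), and each vertical axis starts at 0. Il6ra separates the groups (means 23.6 and 34.9 CPM), while the groups overlap for Col3a1 (23209 and 24576 CPM).

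Several macrophage and protease genes, among them Arg1 and Mmp9, had higher means in the fistula vein without passing the test over all genes. Arg1, the arginase of alternatively activated macrophages, stood at 15.97 CPM ± 6.21 (SD, n = 6) in sham and 92.6 CPM ± 73.6 (SD, n = 6) in AVF-CKD, a log2 fold change of 2.54 ± 0.50 (edgeR adjusted p = 0.368), and Mmp9, which encodes a gelatinase, at 16.7 CPM ± 4.86 and 53.3 CPM ± 27.3, a log2 fold change of 1.67 ± 0.35 (edgeR adjusted p = 0.368). Of the 24 macrophage and monocyte genes 18 had positive fold changes (median 0.20), and Mertk, Itgam and Arg1 passed a threshold of 0.05 adjusted over the list alone, against 0 over all genes tested. The exons of Itgam overlap another gene model over 68.7% of their length, so its counts are uncertain. camera with a preset correlation of 0.01 called this list higher (adjusted p = 9.02e-06), but the adjusted p was 0.536 with an estimated correlation. Neutrophil genes had a median of 0.53, with 12 of 13 positive (adjusted p = 0.00138 with the preset and 0.553 with an estimated correlation). Within title numbers 1 to 3 their median was 0.96, and within numbers 4 to 6 it was 0.22. Their most abundant member S100a9 stood at 84.8 CPM ± 33.0 in sham and 90.2 CPM ± 45.1 in AVF-CKD, with log2 fold changes of 0.98 ± 0.32 and -0.83 ± 0.28 in the same sets of numbers.

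In the chemokine and cytokine list 24 of 37 genes were positive (median 0.18; adjusted p = 0.0243 with the preset and 0.597 with an estimated correlation). Ccl12, a monocyte-attracting chemokine, was at 21.6 CPM ± 5.30 in sham and 11.7 CPM ± 2.33 in AVF-CKD (log2 fold change -0.89 ± 0.18), and Cxcl12 at 238 and 407 CPM (0.77 ± 0.20). Both passed when adjusted over the list alone. Spp1, which encodes osteopontin, stood at 361 CPM ± 119 in sham and 812 CPM ± 503 in AVF-CKD (edgeR adjusted p = 0.422). All 24 interferon response genes had negative fold changes (median -0.40, adjusted p = 3.5e-11 with the preset correlation). With an estimated correlation the adjusted p of this list was 0.536. Ifit3, an interferon-induced antiviral gene, passed when adjusted over the list alone (107 CPM ± 38.6 in sham, 56.9 CPM ± 15.5 in AVF-CKD).

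No gene of the vessel wall lists passed the edgeR test over all genes. Of 19 contractile smooth muscle genes 16 were negative (median -0.21; adjusted p = 4.63e-05 with the preset and 0.536 with an estimated correlation), and Acta2, the smooth muscle actin gene, stood at 954 CPM ± 196 in sham and 734 CPM ± 163 in AVF-CKD (log2 fold change -0.38 ± 0.18, edgeR adjusted p = 0.534). Endothelial genes were negative in 19 of 20 cases, with a median of -0.13 and a 95% interval within 2-fold for each of the 20 (adjusted p = 0.00201 with the preset and 0.553 with an estimated correlation). Venous identity genes had a median of -0.29 (adjusted p = 0.00712 and 0.536 in the same order) and arterial identity genes of 0.14 (0.667 and 0.919). The 30 fibrillar and provisional matrix genes split evenly, 15 positive and 15 negative (median 0.02, adjusted p = 0.999 with the preset correlation), though the list was called lower without AVF-CKD 6 (median -0.097, adjusted p = 0.0094). By contrast, basement membrane genes had a median of 0.12 (adjusted p = 0.0444 and 0.654) and matrix proteases and inhibitors of 0.11 (0.00597 and 0.536), where Mmp9 passed when adjusted over the list alone. Adventitial fibroblast genes had a median of -0.23 (0.0134 and 0.553). Cell cycle genes were positive in 27 of 30 cases, with a median of 0.12 (0.00235 and 0.597) that was 0.25 without sham 5 and 0.064 without sham 1, and Mki67 stood at 78.4 CPM ± 24.8 in sham and 87.9 CPM ± 12.7 in AVF-CKD.

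All 19 fat genes were negative (median -0.86; adjusted p = 2.33e-07 with the preset and 0.553 with an estimated correlation). Adipoq, the adiponectin gene, was at 175 CPM ± 108 in sham and 77.2 CPM ± 21.7 in AVF-CKD, and it and Retn passed when adjusted over the list alone. Oxidative phosphorylation genes were negative in 37 of 37 cases, by a median of -0.14 (1.18e-06 and 0.553) that was 0.10 within title numbers 1 to 3 and -0.43 within numbers 4 to 6, and fatty acid oxidation genes in 23 of 24 (median -0.23; 0.00266 and 0.587). Much of the result for the fat and fatty acid oxidation lists rested on 1 library: Adipoq was at 386 CPM in sham 6 and at 81.0 to 179 CPM in the other sham libraries. Without sham 6 the median of the white and brown fat list was -0.088 (adjusted p = 0.00114 with the preset correlation) and that of the fatty acid oxidation list -0.022 (adjusted p = 0.372, no longer called). Skeletal muscle markers ranged widely within both groups: Ckm, the muscle creatine kinase gene, was at 655 CPM ± 493 in sham and 557 CPM ± 578 in AVF-CKD, and the list had a median of -0.18 (0.667 and 0.919). Within numbers 1 to 3 and 4 to 6 Ckm had log2 fold changes of 1.06 ± 0.91 and -1.86 ± 0.81 (SE), signs shared with the oxidative phosphorylation genes. The ribosomal DNA models held 5.05% to 6.25% of counts in sham and 4.18% to 5.51% in AVF-CKD within numbers 1 to 3. Within numbers 4 to 6 they held 3.89% to 5.075% and 6.22% to 7.46%. In refits over all libraries, chosen after the data were seen, the oxidative phosphorylation list kept its negative median and its call with the preset correlation. This held with muscle and fat scores as covariates and with ribosomal and mitochondrial copies removed. Neither refit was run within the sets of numbers, so whether muscle or ribosomal DNA bears on the opposite signs there was not tested.

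The other lists called with the preset correlation, with the median and then the adjusted p with the preset and with an estimated correlation, were in part lower. These were the unfolded protein response (-0.13; 0.00266 and 0.553), neck glands and epithelium (-1.02; 0.0134 and 0.553), B cells and plasma cells (-0.30; 0.0135 and 0.553) and mast cells (-0.29; 0.0444 and 0.553). The higher ones were cardiac muscle (0.40, 0.00289 and 0.398), erythroid (0.33, 0.0134 and 0.587), circadian clock (0.29, 0.0267 and 0.536), oxidative stress and heme handling (0.18, 0.0135 and 0.553) and hypoxia and glycolysis (0.13, 0.00787 and 0.553). Of the 18 cardiac muscle genes 11 passed the low-count filter, and without a filter the cardiac muscle list had a median of -0.018 and was not called (adjusted p = 0.162). The value for neck glands came from sham 6 (mean log2 CPM of the list 2.78, against -0.76 to 0.74 in the other sham libraries), and without it the neck glands and epithelium list had a median of -0.078 (adjusted p = 0.376, no longer called). Dbp, an output gene of the clock and member of that list, was at 6.15 to 21.4 CPM in sham 4, 5 and 6 and AVF-CKD 6 and at 77.7 to 107 CPM in the other 8 libraries. In total camera with the preset correlation called 11 lists higher and 12 lower of 37 tested. With an estimated correlation none of the 23 held (edgeR-based camera adjusted p from 0.3975 to 0.654), and fry called 0 (lowest adjusted p 0.42 directional and 0.367 mixed). Estimated correlations within lists had a median of 0.318. The lists not called had medians of 0.23 for nerve and Schwann cells, 0.18 for lymphatic endothelium, 0.12 for complement, 0.11 for fistula stenosis candidates, where Mmp9 passed when adjusted over the list alone, 0.09 for leukocyte adhesion, -0.07 for TGF-beta signalling and myofibroblasts, -0.08 for coagulation and platelets, -0.10 for T and NK cells, -0.11 for immediate early genes, -0.13 for shear-responsive endothelium and -0.16 for osteochondrogenic and calcification genes. The sex-linked list had too few tested members for a set test (4), with a median of -0.03. Leaving out sham 1 lowered the number of lists called higher from 11 to 6, and the muscle and fat scores as covariates, chosen after the data were seen, lowered it to 7.

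With the preset correlation, 9 of the 23 called lists were called whichever library was left out, and the call of the other 14 ended without 1 or more of the 12. It ended without sham 6 for neck glands and fatty acid oxidation. For the rest, the libraries are given with the adjusted p without them. They were sham 1 for proliferation (0.0703) and AVF-CKD 2 for venous identity (0.0538). Sham 1 and AVF-CKD 3 ended the call for adventitial fibroblasts (0.0572 and 0.165), and sham 1 and AVF-CKD 4 that for hypoxia and glycolysis (0.0675 and 0.0733). For oxidative stress and heme handling they were sham 5 and AVF-CKD 1 and 3 (0.0685 to 0.131). B cells and plasma cells depended on sham 1 and 5 and AVF-CKD 1 and 3 (0.0535 to 0.12), and mast cells on sham 2, 3 and 4 and AVF-CKD 3 and 6 (0.0977 to 0.202). Cardiac muscle depended on sham 1, 2 and 6 and AVF-CKD 2 (0.0608 to 0.073), erythroid genes on sham 1, 2 and 3 and AVF-CKD 5 (0.0605 to 0.259), and the clock on sham 4, 5 and 6 and AVF-CKD 1, 3 and 5 (0.0547 to 0.106). Chemokines and cytokines depended on sham 1, 5 and 6 and AVF-CKD 3 and 4 (0.0766 to 0.595), and basement membrane genes on sham 2, 3 and 4 and AVF-CKD 4, 5 and 6 (0.0678 to 0.992).

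Medians of called lists also moved by more than 1.5 times when a library was left out. Leaving out sham 1 brought mast cells to -0.45, proliferation to 0.064 and erythroid genes to 0.12. Without sham 2, macrophages and monocytes were at 0.33, interferon response at -0.22 and erythroid genes at 0.18, and without sham 3 erythroid genes were at 0.15. Without sham 4, mast cells were at -0.12, the clock at 0.18 and erythroid genes at 0.57. Without sham 5, proliferation was at 0.25 (adjusted p = 1.44e-12), basement membrane at 0.23, B cells and plasma cells at -0.17, the clock at 0.17 and cardiac muscle at 0.60. Leaving out sham 6 gave endothelium -0.074, basement membrane 0.20, the clock 0.17 and erythroid genes 0.52. Without AVF-CKD 1, endothelium was at -0.079, basement membrane at 0.22 and B cells and plasma cells at -0.16. Without AVF-CKD 2, endothelium was at -0.075, basement membrane at 0.19, hypoxia and glycolysis at 0.060, oxidative phosphorylation at -0.25 and cardiac muscle at 0.24. Without AVF-CKD 3, endothelium was at -0.21, basement membrane at 0.18, adventitial fibroblasts at -0.15, B cells and plasma cells at -0.15 and mast cells at -0.16. Leaving out AVF-CKD 4 gave contractile smooth muscle -0.12 and erythroid genes 0.17. Without AVF-CKD 5, contractile smooth muscle was at -0.39, endothelium at -0.20, adventitial fibroblasts at -0.36, oxidative phosphorylation at -0.068, matrix proteases and inhibitors at 0.069, basement membrane at 0.0017 and erythroid genes at 0.15. Leaving out AVF-CKD 6 gave B cells and plasma cells -0.61, adventitial fibroblasts -0.15 and mast cells -0.17.

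Of the lists not called, 9 were called with the preset correlation when 1 library was left out (median and adjusted p without it). Complement genes were called higher without sham 2 or 3 or AVF-CKD 3 or 6 (0.15 to 0.22; 0.00586 to 0.0242), fistula stenosis candidates without sham 5 or AVF-CKD 1, 2 or 5 (0.089 to 0.18; 0.0245 to 0.0481), and leukocyte adhesion without sham 2 or 3 (0.18 and 0.20, 0.0385 and 0.0341). Shear-responsive endothelium was called lower without sham 1 or AVF-CKD 3 or 5 (-0.14 to -0.15, 0.0228 to 0.0462) and skeletal muscle without sham 3 or AVF-CKD 2 (-0.41 and -0.83, 0.00974 and 0.0135). Osteochondrogenic and calcification genes were called lower without sham 2 (-0.20, 0.0385), T and NK cells without sham 6 (-0.25, 0.0244), and fibrillar and provisional matrix (-0.097, 0.0094) and TGF-beta signalling and myofibroblasts (-0.14, 0.0282) without AVF-CKD 6.

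**Figure D3:**
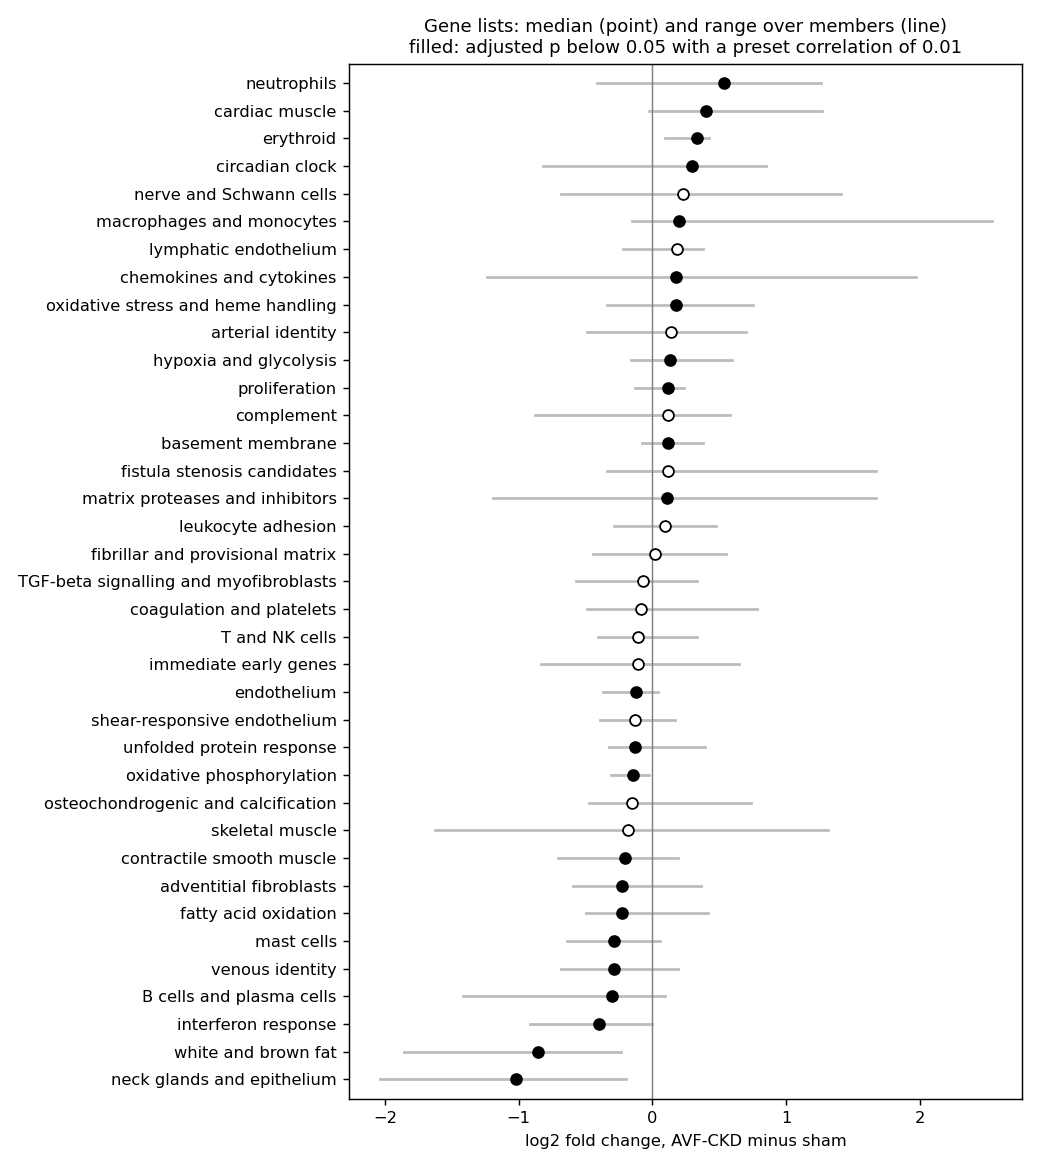
Median log2 fold change (AVF-CKD minus sham) of the tested members of 37 gene lists, with lines from the lowest to the highest member; filled points have an adjusted p below 0.05 in camera with a correlation of 0.01. Medians run from -1.02 for neck glands and epithelium (-0.078 without sham 6) to 0.53 for neutrophils, and no filled list held with an estimated correlation.

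Libraries numbered 1 to 3 and 4 to 6 differed in many genes, and ribosomal protein genes were lower in numbers 4 to 6. With the group in the model, edgeR called 1275 genes higher and 1711 lower in libraries numbered 4 to 6 than in those numbered 1 to 3, a comparison chosen after the data were seen. Genes higher in numbers 4 to 6 had a median length of 6661 bases and those lower of 1859 bases. Ribosomal protein genes were lower in 80 of 85 cases and higher in 0 (median log2 fold change -0.43). Polr2a, the gene of the largest RNA polymerase II subunit, stood at 46.8 CPM ± 1.75 (SD, n = 6) in numbers 1 to 3 and 76.5 CPM ± 18.3 (SD, n = 6) in numbers 4 to 6, and Rps20 at 675 CPM ± 65.9 and 468 CPM ± 43.2. The labels name no batch. Within numbers 1 to 3 the comparison of AVF-CKD with sham (3 against 3) called 0 genes (1988 of 19140 at an unadjusted p below 0.05), within numbers 4 to 6 it called 0 (2032 of 19097), and with the numbers as a term in the pooled fit it called 0 (2529, lowest adjusted p 0.187). Lists called by camera with the preset correlation were 10 higher and 12 lower within numbers 1 to 3, and 8 higher and 7 lower within numbers 4 to 6. With an estimated correlation camera called 0 lists in either set (lowest adjusted p 0.322 and 0.581). Of the 23 lists called in the pooled comparison, 6 had medians of opposite sign in numbers 1 to 3 and 4 to 6. These were erythroid genes (1.28 and -0.14), B cells and plasma cells (-0.89 and 0.023), adventitial fibroblasts (-0.43 and 0.077), proliferation (0.30 and -0.027), basement membrane (-0.088 and 0.30) and oxidative phosphorylation (0.10 and -0.43). The other 17 had medians of the same sign, but not always of like size. They included the clock (0.00071 and 0.82), neck glands (-0.015 and -1.66) and fatty acid oxidation (-0.039 and -0.39). Interferon response (-0.41 and -0.39) had similar medians in both sets. Across 18764 genes, which are not independent replicates, the fold changes within the 2 sets of numbers had a Pearson correlation of 0.02. Arg1 had log2 fold changes of 2.27 ± 0.58 and 2.75 ± 0.74 (SE) in numbers 1 to 3 and 4 to 6, Il6ra of 0.47 ± 0.13 and 0.65 ± 0.09, Spp1 of 1.97 ± 0.47 and 0.14 ± 0.24, and Col3a1 of -0.33 ± 0.23 and 0.44 ± 0.16. Arg1 and Il6ra were picked by their values in these same libraries, with every fistula library above every sham library. Their shared sign in both sets follows from that and is no separate evidence. The interaction of group and number was called for 0 genes by edgeR (1749 at an unadjusted p below 0.05).

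**Figure D4:**
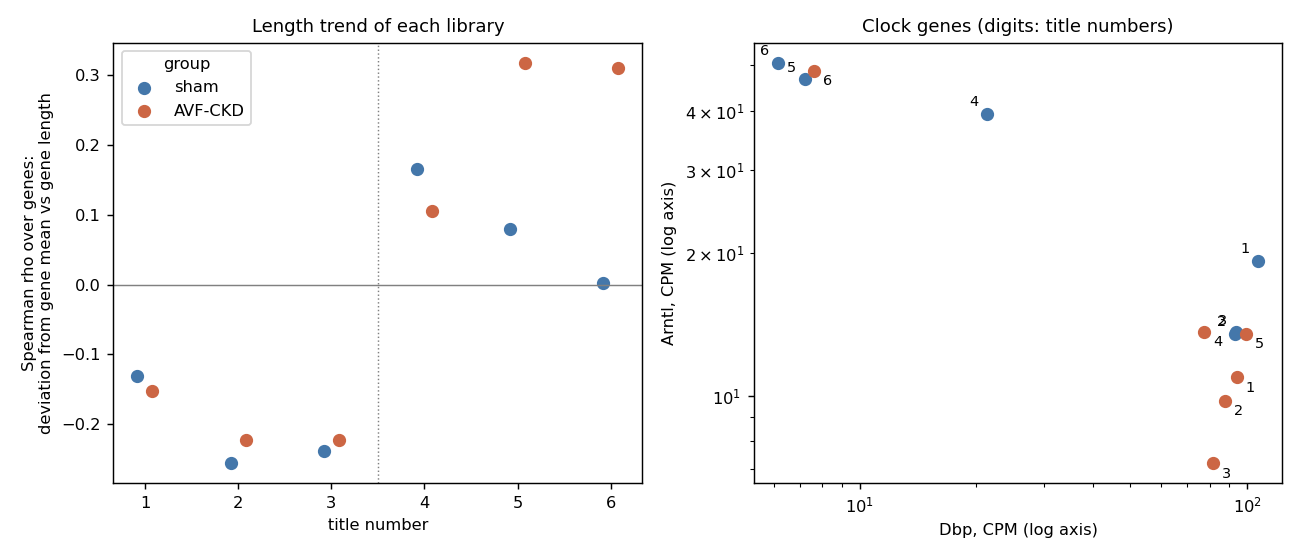
Left, Spearman correlation over genes between gene length and each library's deviation from the gene means, by title number; right, CPM of Dbp and Arntl in each library on log axes. Points are libraries and colours are groups; correlations lie between -0.256 and -0.131 in numbers 1 to 3 and between 0.00197 and 0.318 in numbers 4 to 6.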

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

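The splits for the count of called genes by edgeR, the splits balanced over title numbers, the tests of length as the whole cause and of harvest time for the title numbers, and both tests of Dbp were chosen after the results were seen. The clock, muscle and fat covariates and the comparison of title numbers were chosen after the data were seen. Of 224 groups of 6 values examined, 29 had a library far from the other 5 of its group. For independent groups not picked by their values chance would give about 5%, or 11.2. The groups included genes named after their values were seen, and related genes and lists, so this comparison is not a test of chance.

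A structure of the samples follows the title numbers: of the 100 splits of the libraries that were run, that of numbers 1 to 3 against 4 to 6 called 2615 genes, and the next highest, sham 1, 5 and 6 with AVF-CKD 4, 5 and 6 against the rest, called 249, against 0 for the real groups. A trend on gene length in each library may account for part of it, since removing it left 49.7% of the number of called genes, narrowly under the bound of 50% set in advance, but not for all of it, since 1483 genes were called after it, 1233 of them among the 2986 called before; over the genes called at first the median absolute log2 difference went from 0.36 to 0.27. Removing a trend on GC content left 100.9% of the number, which argues against GC. Harvest time was tested by counting libraries numbered 4 to 6 with Dbp within or above the range of numbers 1 to 3. The count was 1 and decided nothing. Another test, chosen because of that with the values known, used a lower Dbp bound of 60 CPM. It found 2 libraries, AVF-CKD 4 and 5, with high Dbp (77.7 and 99.6 CPM). Their length trends lay above those of all libraries numbered 1 to 3. For these 2 libraries this argues against harvest time as the whole cause. All sham libraries numbered 4 to 6 were low in Dbp (6.15 to 21.4 CPM), so in sham harvest time and title number cannot be told apart. Library batches, RNA quality and separate cohorts of mice stay open, and no biological explanation was tested, since the labels give none.

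For the count of 0 genes past an adjusted p of 0.05, an exchange of labels as what hid 100 or more genes is argued against: over the 36 exchanges of 1 library of each group the highest count was 3 (sham 5 with AVF-CKD 5), although 8 of the 36 gave more than the 1772 genes at an unadjusted p below 0.05 of the real groups (highest 2466, sham 4 with AVF-CKD 3), so that for this count an exchange stays open. Muscle and fat scores as covariates gave 0 genes, and the clock score as a covariate gave 0, so no set of 100 or more appeared with either. The fat and clock lists themselves had shifted medians between the groups, so these covariates can also take up part of a group difference. Whether either hid such a set is therefore not settled. Depth and number of libraries do not limit 2-fold differences for most genes, since the 95% interval excluded them for 86.7%. The share differed by list. It was 4 of 13 neutrophil genes, 15 of 37 chemokine and cytokine genes, 11 of 24 interferon response genes and 2 of 19 fat genes, against 20 of 20 endothelial genes. Where the interval reached 2-fold, a difference of that size stays open. Smaller differences, of which the simulation recovered 34.9% at 1.5-fold, stay open, and so does a true absence of larger ones.

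Other splits of the 12 libraries, the real one included in each count, bear on chance differently by how they treat the title numbers. For the count of called genes they decide nothing, since with a real count of 0 all 100 of 100 must reach it (highest other 2615). Over the 100 splits drawn from all 462, chance cannot be excluded: 16 gave 1772 or more genes at an unadjusted p below 0.05 (highest other 5871), 5 called 23 or more lists with the preset correlation (highest other 26), and with DESeq2 11 called 102 or more genes (highest other 3884). Over 100 drawn from the 200 splits that, like the real groups, have 3 libraries of title numbers 1 to 3 and 3 of 4 to 6 per group, 1 of 100, the real one, reached the genes at an unadjusted p below 0.05 (highest other 1398), 3 of 100 the calls of DESeq2 (the others 163 and 312) and 8 of 100 the lists (highest other 26). The first and second count were thus seldom reached among these splits. Because these splits were chosen after the results were seen, this does not exclude chance. Over all genes the fold changes within the 2 sets of numbers had a Pearson correlation of 0.02. This value weighs all genes equally whatever their counts. Muscle genes that varied within both groups changed sign between the sets, such as Ckm (1.06 and -1.86) and Acta1 (1.33 and -1.42). The correlation therefore cannot decide for or against a group difference. Whether the groups differ beyond chance stays open.

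Dbp, an output gene of the circadian clock, was low in 4 libraries, sham 4, 5 and 6 and AVF-CKD 6 (6.15 to 21.4 CPM, against 77.7 to 107 CPM in the other 8). A different time of day at harvest is a candidate explanation: Arntl, which peaks opposite to Dbp, was higher in each of the 4 (39.5 to 50.6 CPM) than in the other 8 (7.20 to 19.3 CPM), a gap of 1.03 on the log2 scale. Skeletal muscle is argued against, since of the 4 libraries with the highest Ckm, sham 2 had Dbp at 93.3 CPM. The labels give no harvest time, and no biological explanation was tested.

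In this paragraph each library is set against the other 5 of its own group, and highest and lowest mean within that group. AVF-CKD 6 stood apart in Dbp (7.65 CPM), Tef (52.4 CPM, others 127.6 to 165.2), Arntl (48.6 CPM), Npas2 (27.2 CPM, others 1.78 to 4.47), the circadian clock list (mean log2 CPM 4.26) and Tnc (938 CPM, others 291.5 to 376.3). Sham 6 was highest in fat genes: the white and brown fat list had a mean log2 CPM of 6.74 (others 4.07 to 4.75), the fatty acid oxidation list 6.08, Hadha 187 CPM, Ucp1 42.5 CPM (others 0 to 0.503) and Ptger3 21.5 CPM. In AVF-CKD 4, Ucp1 was at 10.5 CPM, Brinp3 at 16.4 CPM and Mup14 at 0.278 CPM. Sham 5 was highest in Tnc (1128 CPM, others 376.8 to 475.7), Fn1 (3355 CPM), the proliferation list (mean log2 CPM 5.21) and Xist (94 counts, others 8 to 13), with Ddx3y, on the Y chromosome, at 3750 counts. Sham 1 was lowest in Spp1 (133 CPM, others 338.1 to 459.5), Arg1 (4.52 CPM, others 14.5 to 22.7) and Brinp3 (3.27 CPM). Sham 3 was lowest in the muscle genes Ckm (54.2 CPM) and Acta1 (99.9 CPM). AVF-CKD 3 was highest in Il7r (49.6 CPM) and lowest in Il6ra (28.6 CPM), and AVF-CKD 5 was highest in Dcn (4198 CPM) and lowest in the hypoxia and glycolysis list (mean log2 CPM 6.05). The lowest B cell and plasma cell list was in sham 4 (0.31), and the lowest immediate early gene list in AVF-CKD 1 (4.97).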

How the results depend on the processing

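The covariates, the title numbers as a term and the removal of ribosomal and mitochondrial copies were chosen after the data were seen. The count of 0 genes higher and 0 lower held under each edgeR alternative with all 12 libraries and with limma voom, and DESeq2 gave 64 and 38. Lists called by camera with a preset correlation stayed between 9 and 12 in each direction under the alternatives that kept all libraries, except for 0 and 0 with an estimated correlation, 0 and 0 with fry, and 7 higher with the muscle and fat scores. These counts cover changes of single calls, given with the adjusted p, and with the CPM filter fewer than 37 lists could be tested. With that filter B cells and plasma cells (0.251) and mast cells (0.173) lost theirs and fistula stenosis candidates (0.0458) gained one. Without a filter cardiac muscle (0.162) and neck glands (0.116) lost theirs and fistula stenosis candidates (0.0484) gained one. Lost calls were basement membrane with 1 surrogate variable (0.0797), mast cells with the block (0.0553) and the title numbers as a term (0.075), and on voom basement membrane (0.531), mast cells (0.122), the clock (0.0596) and neck glands (0.164). Complement (0.0347) gained one with genes of other tissues removed. The clock score ended those of chemokines (0.475), oxidative stress (0.214), fatty acid oxidation (0.0628), the clock (0.607) and neck glands (0.23) and made that of fibrillar and provisional matrix (0.0279). Muscle and fat scores ended those of mast cells (0.102), chemokines (0.293), proliferation (0.0831), oxidative stress (0.0831), fatty acid oxidation (0.233), the clock (0.138), fat (0.128) and neck glands (0.663) and made those of shear-responsive endothelium (0.0321) and T and NK cells (0.0232). The title numbers did not pair the libraries (correlations -0.109 to 0.277, 1 of 6 highest with its own number); a block for them gave 0 and 0 genes and 11 and 11 lists, and moved Hdc to -0.11, Acta1 to 0.038 and the lymphatic endothelium list to -0.040. The first principal component differed by 7.76 over all filtered genes (exact permutation p = 0.578). The cause of the changes of sign was not tested. With 1 surrogate variable they were Acta1 (0.057) and Aldoa (0.0092); with voom Ucp1 (0.26), Acta1 (0.093), Aldoa (0.043) and Hdc (-0.14), and for set tests on voom the lymphatic endothelium list (-0.12) and the fibrillar and provisional matrix list (-0.050). Without a filter it was the cardiac muscle list (-0.018). With the clock score they were the leukocyte adhesion list (-0.0069), the coagulation and platelets list (0.0035), the skeletal muscle list (0.16), Dbp (-0.20), Ddx3y (0.017), Acta1 (0.33), Aldoa (0.069), Hdc (-0.0057), Ucp1 (1.61) and Ube2c (0.16). With muscle and fat scores they were the white and brown fat list (0.020), the fatty acid oxidation list (0.033), the leukocyte adhesion list (-0.053), Ucp1 (2.09), Actc1 (-0.0021), Acta1 (0.034), Hdc (-0.22), Aldoa (0.027), Sdc1 (-0.0086) and Hadha (0.033), where the fat score is the mean of the fat list, so that the value of this list follows from the covariate. With title numbers as a term they were the lymphatic endothelium list (-0.069) and Hdc (-0.050). Leaving out each library gave 0 to 1 genes higher (1, Il6ra, without AVF-CKD 3) and 6 to 11 lists higher (6 without sham 1), the first principal component from -6.86 to 6.36 and the spread between replicates from -5.04 to 1.65. It gave S100a9 -0.19 to 0.26, Il7r -0.12 to 0.20, Hdc -0.35 to 0.15, Aldoa -0.31 to 0.20, Ddx3y -0.10 to 0.041, Ube2c -0.72 to 0.24, Acta1 -0.69 to 0.35, Ckm -0.96 to 0.22, Tnc -0.68 to 0.035, Ucp1 -4.55 to 2.84, Actc1 -0.061 to 0.96 and Sdc1 -0.033 to 0.13. For lists it gave fibrillar and provisional matrix -0.097 to 0.089, T and NK cells -0.25 to 0.055, skeletal muscle -0.83 to 0.32, TGF-beta signalling and myofibroblasts -0.17 to 0.018, coagulation and platelets -0.16 to 0.011, leukocyte adhesion -0.0011 to 0.20 and lymphatic endothelium -0.15 to 0.28. The exons of Ube2c overlap those of Tnnc2, a skeletal muscle list gene on the opposite strand, over 22.8% of their length. The counts of Ube2c are therefore uncertain.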

Other observations

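The comparisons of title numbers were chosen after the data were seen. Ckm ranged from 54.2 to 1655 CPM over the 12 libraries, and 20 of 20 skeletal muscle genes lay on the positive side of the main axis of variation. Ucp1, the uncoupling protein of brown fat, was above 1 CPM in sham 6 (42.5 CPM) and AVF-CKD 4 (10.5 CPM) and at most 0.621 CPM in the others. Between title numbers 4 to 6 and 1 to 3, Npas2 differed by 2.48 on the log2 scale (edgeR adjusted p = 0.00954) and Arntl by 1.5 (0.0105). The 4 libraries low in Dbp carried this: Npas2 was at 16.9 to 27.2 CPM in them, while AVF-CKD 4 and 5 (4.19 and 4.47 CPM) lay within the range of numbers 1 to 3 (1.78 to 4.54 CPM). Of the lists, lymphatic endothelium (median 1.02) and erythroid (0.97) had the highest medians in that comparison, with an adjusted p of 0.777 each with an estimated correlation.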
